A study of Apostichopus japonicus with 12 samples.

How the data were processed

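H3K9ac ChIP-seq was done on intestine of Apostichopus japonicus. The series held 12 samples, 3 control and 3 heat-stress immunoprecipitates and the 6 inputs that belong to them, and groups and replicate numbers were taken from the labels. Per the labels, chromatin was crosslinked with formaldehyde and sheared to 200–500 bp, 2% was kept as input, and an antibody against acetylated lysine 9 of histone H3 was used. Libraries were sequenced as paired ends of 150 bases, per the labels. The temperature of the control group is not stated in the labels. Peak lists of the 6 immunoprecipitates were analysed, and the inputs entered only through them, since the peak names pair each immunoprecipitate with its own input and replicates were not pooled. The submitters' processing notes name BWA, SAMtools 1.3.1 and MACS2 2.1.1.20160309. The genome build is not given in the sources used here. Coordinates are given as the files name the scaffolds, counted from 1.

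The deposited score of a peak is the whole-number part of 10 times its −log10 q, as checked on the values, and was not used further. The deposited fold is the caller's ratio of the fragment pileup to the local background at the summit, each with a pseudocount of 1. The deposited −log10 p and −log10 q values come from the authors' peak caller, and the lowest −log10 q in the lists lay between 1.30 and 1.33, so each list ends near a q of 0.05. These values are the authors' and were used to describe, rank or filter peaks within a list, with the following uses across lists. The alternative fold and −log10 q thresholds and the common −log10 p cutoff were the same for every list. A −log10 q of at least 20 was set for both of the longest lists when they were compared. Fold and −log10 p also served to recover the depths that are compared between libraries. Because each list has its own depth and its own p cutoff, a peak missing from a list can still have had signal below the threshold.

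Depth was recovered from the lists. The fold and the −log10 p of a peak together fix its fragment pileup and its background under the caller's Poisson model, and a solution with whole fragments was found for 100% of peaks in all 6 lists, within 0.002 in −log10 p. In heat replicate 3 the pileups were whole multiples of 0.988, as when the immunoprecipitate is scaled down to its input, and in the other libraries the step was 1. The lowest background shared by many peaks is the genome-wide mean coverage of the scaled input, which was used as each library's depth. Input coverage, from the step between backgrounds, was 1.64, 1.56 and 1.88 fragments per position for control replicates 1, 2 and 3 and 1.89, 1.83 and 1.83 for heat replicates 1, 2 and 3. Only 51.9% to 62.8% of the backgrounds fitted lay on that step, and its fit was not simulated, so input coverage is an estimate. On simulated data of 2000 peaks for each kind of scaling, pileup and background came back for 100%, and all of 300 planted regions were found. Wilson 95% intervals and fragment counts cover counting error only.

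Peaks of all 6 lists that overlapped by at least 1 bp were merged into regions, and a library was scored as present where it had a peak in the region. Random expectations came from 100 seeded placements of each list's peaks on the same scaffolds, taken as far as their last peak (610.6 Mb in all). The number of peaks and the covered length were compared as mean log2 values, the median width as it stands, and the similarity of libraries as the mean Jaccard index within minus between groups, each with a two-sided exact permutation test over the libraries. Regions with a peak in all 3 libraries of a group and none of the other were counted and set against the 10 splits of the 6 libraries. A further 1000 draws swapped region memberships while keeping each list's length and each region's number of libraries. To match the genome background, fragments at each listed peak were thinned at random, 100 times, to the lowest background coverage of 0.730, and peaks were kept at a common −log10 p of 4.17, the highest of the lists' own lowest values.

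Regions are named by a rule fixed before the data were examined, as were the permutation tests, the counts of group-only and shared regions with their random placements and splits, and the alternatives listed next; the closing section names what was added later. The rule takes up to 10 regions found in all 3 libraries of a group and none of the other, ordered by mean within-list percentile of fold and filled from regions with 1 library of the other group, up to 10 regions found in all 6 libraries, ordered by their lowest percentile, and the peak of highest fold in each library. Alternatives were a −log10 q of at least 5, a fold of at least 3, merging within 500 bp, a reciprocal overlap of 50%, presence in 2 of 3 libraries, lists of equal length, leaving out each library, and a replicate block. Planned counts at promoters and genes and for fixed gene lists were not run, because no annotation of the assembly named in the files was used here. The gene table at hand is of another assembly (ASM3797524v1), and 0 of its 30661 genes name a scaffold of the peak lists, so no gene names are given. Odds ratios for peaks on a high local background were taken by direct overlap of peaks in each control library and combined with the Mantel-Haenszel method. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.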

Results

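Acetylation of histone H3 at lysine 9 (H3K9ac), a mark known from active promoters, was measured by ChIP-seq in the intestine of the sea cucumber Apostichopus japonicus, in a control group and in a heat-stress group. The water of the heat-stress group had been warmed from 18 to 26 °C at 2 °C per hour and was then held at 26 °C for 48 h before the intestine was taken. Per the labels, the design examined H3K9ac in both groups. Peak lists were used from 3 control and 3 heat-stress libraries, each called by the authors against its own input DNA, and together they held 44001 peaks on 2176 scaffolds. Depth differed between the libraries. The genome background recovered from the lists was 0.730, 0.758 and 1.69 fragments per position in control replicates 1, 2 and 3, and 1.39, 1.203 and 1.85 in heat replicates 1, 2 and 3. The median peak rested on 13, 12 and 18 fragments in the controls and on 15, 14 and 22 in the heat libraries. The labels do not say that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Each main test between the groups set 3 libraries against 3, which cannot give a p below 0.1.

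The first comparison asked whether heat stress changed how much of the genome carried H3K9ac peaks. Heat replicates 1 and 2 had fewer peaks than any control, 1180 and 929, whereas heat replicate 3 had 17932, the most of all 6 libraries. The controls had 5614, 1828 and 16518 peaks in replicates 1, 2 and 3. The mean was 7987 ± 7627 peaks in the controls and 6680 ± 9745 in the heat libraries (SD, n = 3 each). On the log2 scale the heat libraries stood at −1.04 relative to the controls, a ratio of geometric means of 0.488, with SDs of 1.59 in the controls and 2.37 in the heat libraries. This difference was smaller than the spread between replicates (two-sided exact permutation test, p = 0.6). Peaks covered 1965, 508 and 7551 kb in the controls and 330 kb, 254 kb and 9151 kb in the heat libraries, a log2 difference of −1.10 with the same exact permutation p of 0.6. The median peak width was 272 ± 43.5 bp in the controls and 261.5 ± 68.9 bp with heat (SD, n = 3 each), a heat minus control difference of −10.5 bp (two-sided exact permutation test, p = 0.8). Without heat replicate 3 the log2 difference in peak number was −2.40, without control replicate 2 it was −1.84, and without control replicate 3, heat replicate 1 or heat replicate 2 it was −0.25, −0.44 or −0.27. That in covered length ranged from −0.13 without control replicate 3 to −2.76 without heat replicate 3. The width difference turned positive without control replicate 3 (11 bp), heat replicate 1 (10 bp) or heat replicate 2 (8.75 bp).

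**Figure D1:**
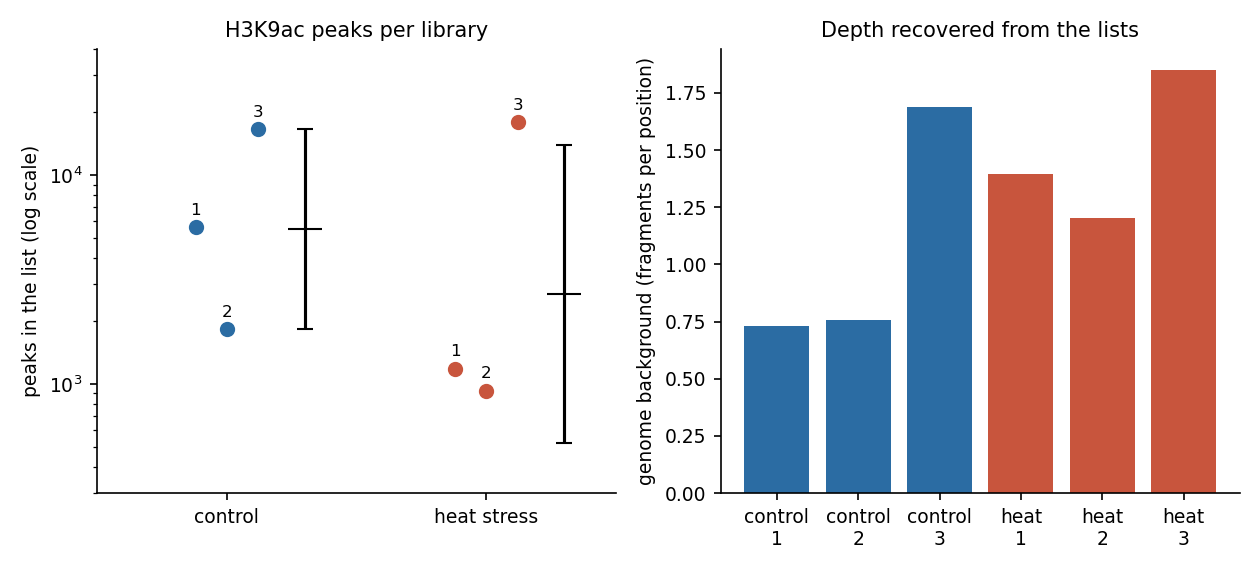
Left, H3K9ac peaks per library on a log axis, with points numbered by replicate and bars giving the geometric mean ± 1 SD of the log2 values (n = 3 per group); the heat libraries lie at 1180, 929 and 17932 peaks, on both sides of all controls. Right, the genome background in fragments per position recovered from each list, from 0.730 in control replicate 1 to 1.85 in heat replicate 3.

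The peak with the highest fold enrichment in each library, as the authors' caller gave it, lay in each of the 6 libraries in a region that at least 1 library of the other group also had. In heat replicate 3 it lay on MRZV01000083.1 at 95261–97298 (fold 25.4) and belonged to a region present in all 6 libraries. In control replicate 3 it lay on MRZV01001263.1 at 89749–91136 (fold 22.9), also in a region present in all 6 libraries, where heat replicate 3 reached a fold of 21.5. In heat replicate 2 it lay on MRZV01000785.1 at 247835–248029 (fold 9.49), within a merged region at 245721–248072 where all 6 libraries had a peak. Control replicate 2 and heat replicate 1 had their peaks elsewhere in that region, outside the interval of this peak. In control replicate 1 the peak of highest fold lay on MRZV01001257.1 at 170866–171433 (fold 21.0), within a region also called in control replicate 3 and heat replicate 3. The remaining pair were narrow sites called in all 3 controls and in heat replicates 1 and 2 but not in heat replicate 3. One was on MRZV01000163.1 at 231913–232130, with a fold of 24.6 in heat replicate 1, 7.26 in heat replicate 2 and 15.2, 17.5 and 8.18 in control replicates 1, 2 and 3. The other was on MRZV01000084.1 at 424095–424355, with folds of 4.05, 18.3 and 10.0 in control replicates 1, 2 and 3 and of 10.0 and 7.06 in heat replicates 1 and 2. At this site the peak of control replicate 1 lay on a local background of 9.36 fragments. That is more than 10 times the genome background of that library, the limit used below for a high local background. Folds are given per library as descriptions and were not tested between libraries, because lists of different depth do not share a scale. No annotation of this assembly was used, so whether a region lies in a promoter, exon, intron or intergenic sequence was not analysed here.

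The next comparison asked whether libraries of the same group shared more peak positions than libraries of different groups. No such excess was found in the mean over all pairs. The mean Jaccard index, the bases shared over the bases covered by either list, was 0.0967 ± 0.0704 over the 6 pairs within groups and 0.118 ± 0.115 over the 9 pairs between groups (SD). The difference of −0.0210 was not distinguishable from other splits of the libraries (two-sided exact permutation test, p = 1). With each list held to its 929 most significant peaks the difference was −0.0047 (exact permutation p = 1), and the highest pair within a group was then heat replicates 1 and 2, at 0.168. The most similar pair was control replicate 3 and heat replicate 3, at 0.399, and 62.3% of the peaks of control replicate 3 were overlapped by a peak of heat replicate 3 (Wilson 95% interval 61.5–63.0%). The short lists were largely contained in the long ones. Control replicate 3 overlapped 79.9% of the peaks of control replicate 1, 83.8% of those of control replicate 2, 81.1% of those of heat replicate 1 and 82.1% of those of heat replicate 2. Heat replicate 3 overlapped 84.0%, 84.5%, 83.2% and 84.4% of the same 4 lists. When peaks were placed at random on the same scaffolds, 2.93–3.72% of the regions of these 4 lists were shared with a replicate 3 list. Heat replicates 1 and 2 had a Jaccard index of 0.163, and 33.4% of the peaks of heat replicate 2 were overlapped by heat replicate 1 (Wilson 95% interval 30.4–36.5%). These intervals cover counting error only. The sign of the difference was positive when the share of the shorter list replaced the Jaccard index (0.0625) and when heat replicate 3 was left out (0.0575, exact permutation p = 0.2). Without both libraries numbered 3 the difference was 0.0464, in a comparison of 2 libraries against 2.

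**Figure D2:**
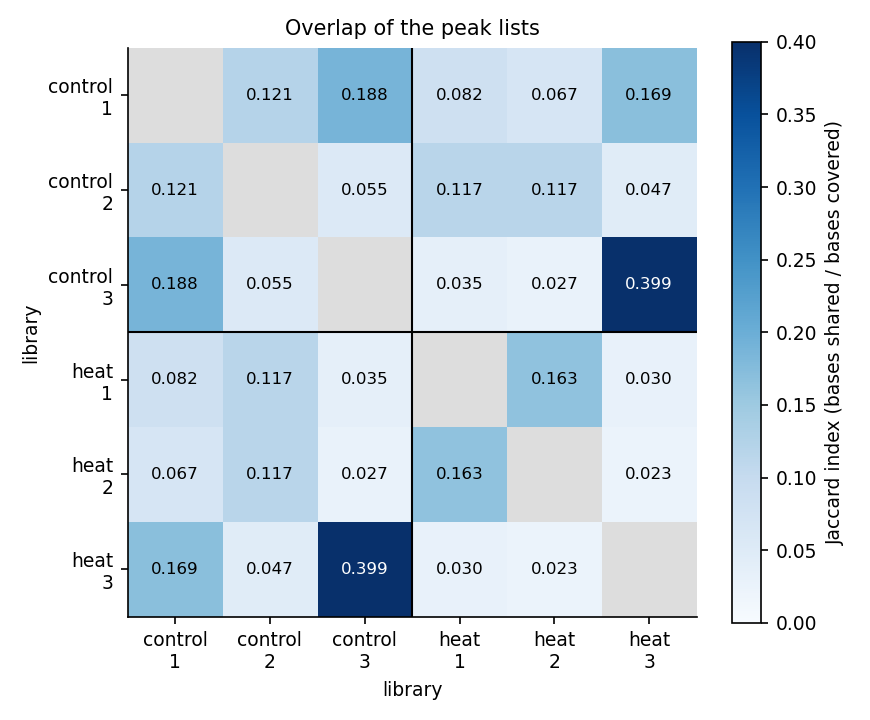
Jaccard index (bases shared over bases covered by either list, no unit) for each pair of the 6 libraries, with black lines dividing controls from heat libraries. The highest value, 0.399, is between control replicate 3 and heat replicate 3, and the highest within a group is 0.188, between control replicates 1 and 3.

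Regions that carried H3K9ac peaks in every control and heat library held wide peaks, and their peaks had the highest median fold of any class of sharing in each library except control replicate 2. Merging overlapping peaks gave 24534 regions, and 174 of them, on 161 scaffolds, had a peak in all 6 libraries, against 0 in each of 100 random placements. The region ranked first was MRZV01000092.1 at 188060–189117, with its highest fold at 10.4, 7.77 and 9.82 in control replicates 1, 2 and 3 and at 7.68, 6.90 and 12.4 in heat replicates 1, 2 and 3. MRZV01000154.1 at 237257–243324 was a domain of 6068 bp, with highest folds of 8.49, 9.11 and 14.3 in the controls and 6.84, 6.63 and 9.55 in the heat libraries. MRZV01000331.1 at 47886–53870 (5985 bp) and MRZV01000105.1 at 620086–624595 (4510 bp) were also broad, and MRZV01000059.1 at 629761–633283 spanned 3523 bp. On MRZV01000785.1 a region at 248248–248846 lay next to the one at 245721–248072, and both had peaks in all 6 libraries. MRZV01001602.1 at 186829–187101 was only 273 bp wide, with a fold of 15.2 in control replicate 3 and 16.8 in heat replicate 3. The remaining named regions of this class were MRZV01002209.1 at 58512–59774, MRZV01000083.1 at 95261–97594 and MRZV01000296.1 at 713807–714962. The 174 regions had a median width of 1979 bp (quartiles 1318 and 2977 bp), a width that merging peaks of 6 lists raises by construction. Single peaks in them, among which wide peaks are favoured because they overlap others more easily, had median widths of 507, 312.5 and 1116 bp in control replicates 1, 2 and 3 and 324, 289 and 1627 bp in heat replicates 1, 2 and 3, against 209, 173, 225, 180, 167.5 and 239 bp for peaks found in that library alone. In heat replicate 3 the median fold was 9.09 for peaks in these regions and 4.24 for peaks found in that library alone. In control replicate 3 these values were 7.63 and 3.88. The contrast was smaller in the shorter lists, at 5.72 and 4.76 in control replicate 1 and 5.10 and 4.55 in control replicate 2. In heat replicates 1 and 2 it was 4.52 and 4.05, and 4.52 and 4.37. The count was 288 without heat replicate 1 and 330 without heat replicate 2, and 31 when a reciprocal overlap of 50% was required.

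Regions with a peak in all 3 heat libraries and in no control numbered 4. They were MRZV01000755.1 at 170533–172523, MRZV01000041.1 at 435200–436135, MRZV01000084.1 at 759153–759639 and MRZV01001018.1 at 136614–136929. MRZV01000755.1 held 2 peaks in heat replicate 1 (highest fold 5.25), a single peak of 1788 bp in heat replicate 2 (fold 4.27) and 3 peaks in heat replicate 3 (highest fold 3.95). At MRZV01000041.1 the folds were 4.46, 5.36 and 3.39 in heat replicates 1, 2 and 3, at MRZV01000084.1 they were 4.05, 4.37 and 5.14, and at MRZV01001018.1 they were 4.56, 3.30 and 5.44. Their folds lay at mean within-list percentiles of 44.6 to 51.3, with the highest single peaks at 79.7 (MRZV01000041.1 in heat replicate 2) and 78.1 (MRZV01000755.1 in heat replicate 1), and the −log10 q values ran from 1.60 to 9.13. By the rule, the regions named next were the highest-ranked of the 24 regions with a peak in all 3 heat libraries and in 1 control. Their higher rank than the heat-only regions in the heat lists thus follows in part from this selection. At MRZV01000054.1, 139545–140635, the folds were 7.68, 6.81 and 12.6 with heat, and control replicate 3 had a peak of fold 6.35. At MRZV01000101.1, 412152–412802, the folds were 7.52, 7.44 and 5.93 with heat and 6.78 in control replicate 3. At MRZV01000578.1, 767658–767943, they were 6.23, 4.89 and 9.39 with heat and 6.94 in control replicate 1. Next in rank were MRZV01000315.1 at 1050204–1050643, MRZV01000139.1 at 392346–393867 and MRZV01000670.1 at 127008–128505. In each of them control replicate 3 was the control with a peak. Between the lists of similar length, the fold percentiles at these 3 regions were 99.1, 93.0 and 83.8 in control replicate 3 and 80.5, 93.3 and 85.2 in heat replicate 3. At MRZV01000315.1 the fold was 12.2 in control replicate 3 and 5.29, 4.75 and 7.08 in heat replicates 1, 2 and 3. Random placement gave a mean of 0.28 heat-only regions, with 2 as the highest of 100 draws, and draws that kept list lengths and region totals gave 1.02 (central 95% 0 to 3). With 3 libraries per group Fisher's exact test on a single region cannot go below 0.1, so no region was called different, and a library without a listed peak was not shown to lack the mark.

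Regions with a peak in all 3 controls and in no heat library numbered 14. The first by rank was MRZV01002451.1 at 43035–43467, with folds of 7.93, 5.85 and 6.55 in control replicates 1, 2 and 3. At MRZV01002761.1, 7224–7664, the folds were 7.40, 5.30 and 9.31, and at MRZV01001421.1, 135870–136254, they were 5.62, 6.26 and 5.15. At MRZV01000299.1, 717049–717338, control replicate 1 reached a fold of 8.67, and at MRZV01001711.1, 120003–120837, control replicate 3 reached 10.7 on 29 fragments while control replicate 1 had 3.41 on 10 fragments. The other named regions were MRZV01001619.1 at 38566–39084, MRZV01000134.1 at 376804–377701, MRZV01000800.1 at 369966–370374, MRZV01001528.1 at 102–1211 and MRZV01000946.1 at 75336–75789. MRZV01000946.1 was the lowest of these, with folds of 5.29, 4.61 and 2.82. MRZV01002006.1 at 78209–78456, chosen after its values were seen, lay on a local background of up to 44.8 fragments, with folds of 2.36 to 3.16. Across the 14 regions the folds ran from 2.36 to 10.7 and the −log10 q from 1.60 to 21.6. Random placement gave a mean of 1.16 control-only regions, with 4 as the highest of 100 draws, whereas draws that kept each list's length and each region's number of libraries gave a mean of 25.7 (central 95% 17 to 36), above the 14 observed. Of the regions with a peak in all 3 controls, 557 had a peak in 1 heat library, 272 in 2 and 174 in all 3.

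Both counts of group-only regions moved with the libraries included. Control-only regions numbered 567 without heat replicate 3, 254 without control replicate 2, 68 without control replicate 1 and 25 without control replicate 3. Heat-only regions were 33 without heat replicate 2, 28 without heat replicate 1, 25 without control replicate 3, 13 without heat replicate 3 and 7 without control replicate 1. When each list was held to its 929 most significant peaks, the order turned, with 18 heat-only and 11 control-only regions. At a −log10 q of at least 5 there were 0 heat-only and 2 control-only regions. A reciprocal overlap of 50% gave 2 and 48.

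**Figure D3:**
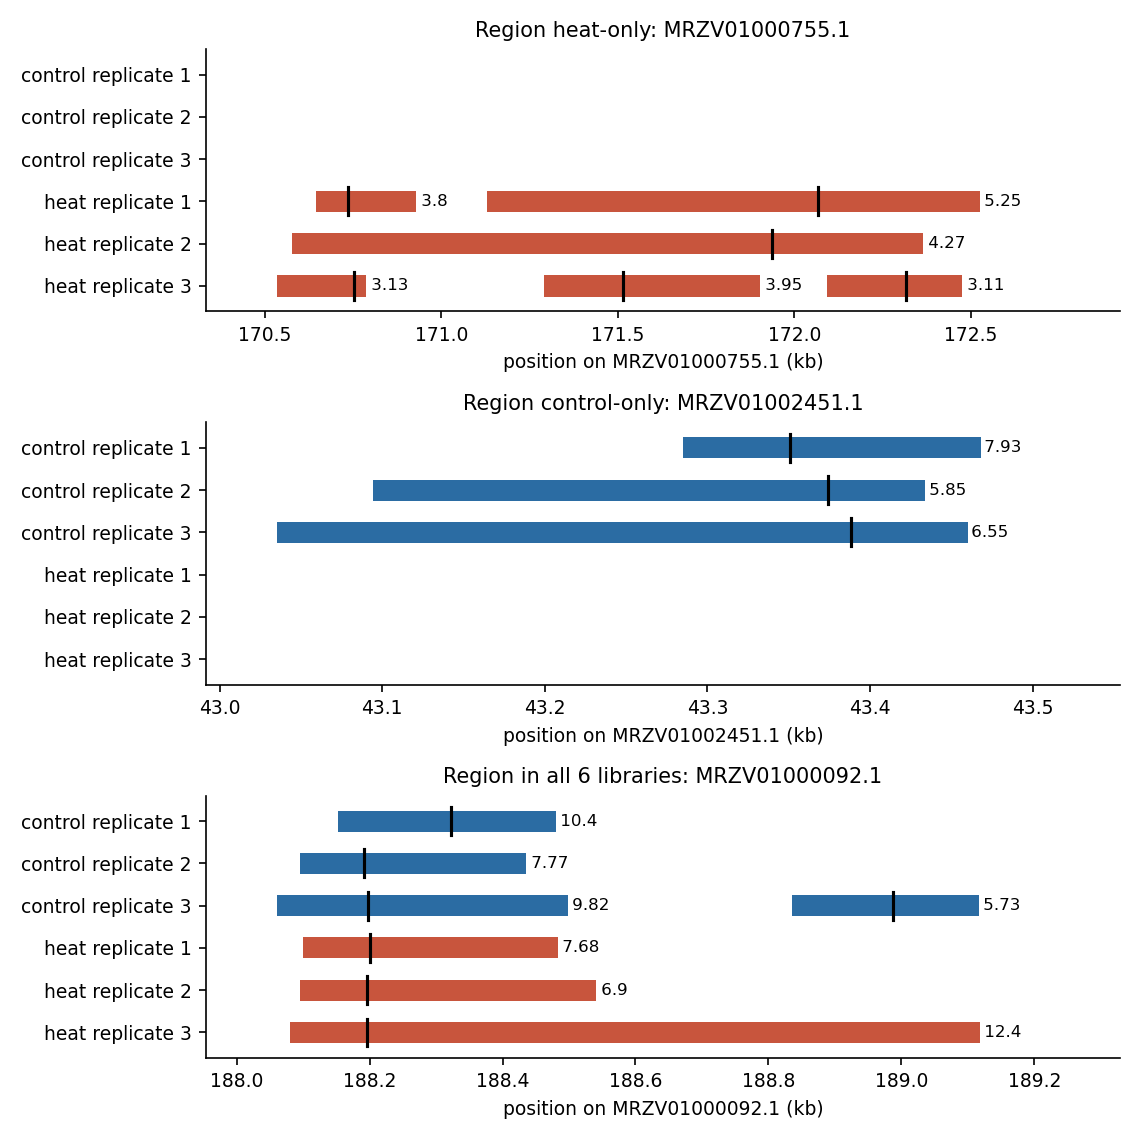
Peaks (bars), summits (black ticks) and fold enrichment (numbers) per library at the first-ranked heat-only, control-only and fully shared regions, with scaffold position in kb on the horizontal axis and the 6 libraries on the vertical axis. MRZV01000755.1 has peaks in the heat libraries alone (folds 3.11 to 5.25), MRZV01002451.1 in the controls alone (5.85 to 7.93), and MRZV01000092.1 in all 6 libraries (5.73 to 12.4).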

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

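Thinning to the same genome background, the common p cutoff, a fold of at least 6, leaving out high-background peaks and leaving out both libraries numbered 3 were chosen after the results were seen; the other alternatives were planned. The log2 difference in peak number stayed negative in all 15 alternatives (−0.25 to −2.40 when 1 library was left out) and that in covered length in all 11 (−0.13 to −2.76), with exact permutation p-values from 0.2 to 1 for these, for peak width and for similarity. Without both libraries numbered 3 these tests set 2 libraries against 2. Each exact permutation p was then 0.333, the smallest that design allows. The width difference ranged from −50.2 to 11 bp with 1 library left out and was positive without control replicate 3 (11), heat replicate 1 (10) or heat replicate 2 (8.75). The similarity difference ranged from −0.0558 to 0.0575 with 1 library left out, and was positive without heat replicate 3 (0.0575), for the share of the shorter list (0.0625), with the replicate block (0.0196) and without both libraries numbered 3 (0.0464); with lists of equal length it was −0.0047. Deviations of region presence from the group means correlated at −0.179, −0.131 and −0.327 between same-numbered libraries of the groups. Between differently numbered libraries of the groups they correlated at −0.211 to 0.274. Since 58.2% of regions had a peak in 1 library only, long lists tend to correlate negatively in this measure. The libraries numbered 3 had the highest Jaccard index of all pairs (0.399), but unequal list lengths cap this index. With each list held to its 929 most significant peaks it was 0.266 for this pair. Control replicate 1 then overlapped heat replicate 3 more (0.150) than heat replicate 1 (0.109), and control replicate 2 overlapped heat replicates 1 and 2 alike (0.115 each). These values do not decide whether the numbers pair the samples, and the numbers were not taken to do so. With 1 library of each group per block, the block cannot change these mean differences. It left the peak number at −1.04 (exact p = 0.5), the covered length at −1.10 and the width at −10.5 bp. Its unchanged signs are thus no separate support. Heat-only, control-only and fully shared regions numbered 2, 48 and 31 at a reciprocal overlap of 50%; 0, 2 and 32 at a −log10 q of at least 5; and 66, 319 and 950 when 2 of 3 libraries sufficed. With lists of equal length they numbered 18, 11 and 52, and without both libraries numbered 3 they numbered 35, 591 and 179. With 1 library left out they ranged from 4 to 33, from 15 to 567 and from 174 to 330, fewer lists having to match. The cause of the other changes was not tested. Promoter, gene and gene list results were not run. The median peak rested on only 12 to 22 fragments, so depth may limit the lists. List length did not follow depth alone, since heat replicates 1 and 2 were deeper than control replicates 1 and 2 but had shorter lists.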

Other observations

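The comparison of the longest lists, the count by scaffold, the spacing of peaks, the draws that keep list lengths and the permutation test as a test of heat stress for the shortest lists were brought in after the results they bear on were seen; the values of the high-background test per library and their combination were added after its pooled result was seen. The thinning and common-cutoff tests were set after the lists were examined but before their own results.

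The longest lists, control replicate 3 and heat replicate 3, differed mostly at weak peaks. Of the control replicate 3 peaks with a −log10 q of at least 20, 41 of 938 (4.37%, Wilson 95% interval 3.24–5.88%) had no region in heat replicate 3, and of those of heat replicate 3, 164 of 2001 (8.20%, 7.07–9.48%) had none in control replicate 3. The scaffold with most of the latter was MRZV01000850.1, with 9 strong peaks of heat replicate 3 absent from control replicate 3. Its strongest were at 392919–393150 (fold 14.4, −log10 q 56.9) and at 509355–509724 (fold 7.27, −log10 q 48.1). On this scaffold heat replicate 3 had 44 peaks, control replicate 3 had 16, control replicate 1 had 14 and the other 3 libraries had 0. The scaffold with the next most strong peaks of this kind, MRZV01000385.1, had 4. Over all peaks on MRZV01000850.1, heat replicate 3 held 73.3% of those of the pair of longest lists against 52.1% by list length (two-sided exact binomial p = 0.00107, and 1 after Bonferroni correction over 2176 scaffolds), a test that treats clustered peaks as independent; the concentration of the strong peaks was not tested. This compares 2 libraries, not the conditions.

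H3K9ac peaks came in clusters in every library. The share of neighbouring peaks on a scaffold lying within 1000 bp of each other was 22.0%, 17.6% and 29.6% in control replicates 1, 2 and 3 and 24.4%, 29.1% and 30.9% in heat replicates 1, 2 and 3, against 0.855% to 6.26% when peaks were placed at random. The median summit distance within these clusters was 668 to 795 bp, a value bounded by the 1000 bp limit and the peak widths. MRZV01000154.1 at 237257–243324 is an example, with 7 separate peaks in heat replicate 1 and a single peak of 5134 bp over most of it in heat replicate 3. Separate sites were thus not told apart from broad domains called in parts.

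Peak lists of heat replicates 1 and 2 were shorter than any control list, and the replicate 3 lists were the longest in both groups. Heat replicates 1 and 2 were deeper than control replicates 1 and 2 (1.39 and 1.203 against 0.730 and 0.758). Depth of the immunoprecipitates thus ran against their shorter lists in this comparison. After the fragments at listed peaks were thinned to the same genome background, they kept 691 and 655 peaks against 1789 in control replicate 2, a ratio of 0.386. Thinning only removes listed peaks, mostly from the deeper libraries, so this ratio could hardly rise and is no test of depth. The common p cutoff alone kept 1175 of 1180 peaks of heat replicate 1 and 1824 of 1828 of control replicate 2, a ratio of 0.644. The cutoff therefore does not account for the difference. For the long replicate 3 lists, depth of the immunoprecipitates was not the whole reason. Control replicate 3 kept 9435 peaks after thinning against 5428 in control replicate 1, a ratio of 1.74. An effect of heat on heat replicates 1 and 2 cannot be told apart from variation between samples, because heat replicate 3 went the other way and the exact permutation test over all 6 libraries gave p = 0.6 in a design that allows none below 0.1. A different yield of the immunoprecipitation may also underlie the list lengths. In the regions shared by all 6 libraries the median folds were 5.72, 5.10 and 7.63 in control replicates 1, 2 and 3. In heat replicates 1, 2 and 3 they were 4.52, 4.52 and 9.09. These medians ran in the order of list length. Folds of lists with different depths and cutoffs do not share a scale, however, so yield was not tested by them.

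The 18 regions confined to a group, 14 control-only and 4 heat-only, were set against the other ways of dividing the 6 libraries. Of the 10 splits, 5 gave 18 or more, the real one included; 10 splits are too few for a share under 0.05. The highest other split gave 2318 and sets the 3 longest lists (control replicates 1 and 3 and heat replicate 3) against the 3 shortest. Draws that keep list lengths and region totals came near this count, at 2116 (central 95% 2084 to 2146), so list length has a large part in it. The observed 2318 lay above that range, so list length alone did not give it. These draws gave 25.7 ± 4.99 control-only regions (SD over 1000 draws, central 95% 17 to 36), so the observed count was 0.545 of the mean, and 1.02 ± 1.04 heat-only regions (0 to 3), so the observed count was 3.91 times the mean, and 2.4% of draws reached it. For regions merged at 1 bp, both counts thus lay outside the central 95% of these draws, although the total of 18 against 26.7 lay just inside its own (17.975 to 37). The draws treat regions as independent although peaks came in clusters, and they were added after the counts were seen. They therefore do not exclude chance for either count. Sets of 3 libraries that mix the groups showed both a deficit (13 against 32.9 for control replicates 1 and 2 with heat replicate 3) and an excess (6 against 0.136 for control replicates 1 and 2 with heat replicate 2). Such departures therefore also arise across groups, and what sets them stays open. At a reciprocal overlap of 50% the counts were 48 control-only and 2 heat-only, and no such draws are given for that setting.

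A small set of peaks lay on a local background of at least 10 times the genome background. They numbered 41, 58 and 38 in control replicates 1, 2 and 3 and 16, 33 and 55 in heat replicates 1, 2 and 3; MRZV01000861.1 at 99134–99624 had such peaks in 4 libraries and MRZV01000062.1 at 51277–51526 in 5. Peaks of heat replicate 1 or 2 overlapped 19 of 41 such peaks of control replicate 1 against 898 of 5573 others (odds ratio 4.50, 95% interval 2.42–8.34, two-sided Fisher's exact p = 6.23e-06), and 23 of 58 of control replicate 2 against 501 of 1770 others (1.66, 0.974–2.85, exact p = 0.0755), which combine to 2.42 (Mantel-Haenszel, 1.62–3.63). This is consistent with sequence held in more copies than the assembly shows, which could recur at fixed positions in both groups, although the interval of control replicate 2 includes 1 and only 33.3% of these peaks were overlapped by a replicate 3 list, against 90.6% of the others. No biological explanation was tested for them.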
